A study of Gossypium hirsutum with 16 samples.

How the data were processed

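Messenger RNA libraries from the shoot apex of cotton seedlings were analysed, 16 in all, 4 for each of 3798 control, 3798 silenced, JX control and JX silenced. Groups and replicate numbers were taken from the titles, and each column was matched to its sample by the code in the sample's description. Per the labels, RNA was extracted with a plant RNA kit, libraries followed Illumina's standard procedure, and the series design names an Illumina HiSeq sequencer.

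The authors deposited 1 table of FPKM (fragments mapped to a gene, scaled by the gene's length and by all mapped fragments of the library), with a value for each of 70422 gene IDs in each library. The unit comes from the name of the deposited table and from its values, which are not whole numbers and total 552185 to 603167 per library. The aligner, counter, genome build, annotation, read length and strandedness are not given in the sources used here. Reads shared by near-identical copies of a gene, which are common between the A and D subgenomes, could have been split or dropped in that counting, and reads of overlapping genes on opposite strands could have been joined. An FPKM of 0 is therefore described as listed at 0. FPKM are relative to the mapped fragments of a library, so a few genes at a very high level could lower the rest, and the 10 highest genes held between 2.21% and 3.44% of the total in a library.

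Because FPKM are not counts, no count model was used. Relative depth was estimated from genes under 0.5 FPKM in every library, as the most frequent ratio between libraries, and the ratios of all pairs of libraries fitted together within a log2 difference of 1.3e-05. Reads were not recovered, since only 13.0% of 65419 low values lay within 0.02 of a whole multiple of the lowest value of their gene, where evenly spread values give 4%. Absolute depth, and with it any limit from counting error, is unknown. Columns were compared, and 0 pairs of libraries held identical values.

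Genes at or above 0.5 FPKM in at least 4 of the 16 libraries were tested, 55040 in all, on log2(FPKM + 0.5). Limma 3.58.1 in R 4.3.3 was fitted to all 16 libraries with 1 mean per group, so that the groups share 1 estimate of the spread, with a trend in the prior variance and robust estimation. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The comparisons were silenced minus control in each strain, their mean, their difference (JX minus 3798), and JX minus 3798 in controls. These, the filter, the pseudocount and the alternatives were fixed before the data were examined. The comparison of JX with 3798 in silenced libraries was added later. On simulated data for the silencing comparison in 3798 over 55040 genes, the procedure recovered 72 of 100 genes changed by a log2 of 1 and 97 of 100 changed by a log2 of 2, with 7 false calls. The simulated noise was normal and independent between genes and libraries, with no deviating library and no other difference between groups. These rates need not hold for the real data.

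The IDs were looked up in a table of 99454 RefSeq genes of assembly Gossypium_hirsutum_v2.1, and 0 matched. The planned report of BRC1-type genes and the tests of 28 gene lists need gene names and were not run. By the rule set for this case, the text names per planned comparison the 2 IDs with the smallest p that rose and the 2 that fell, among those passing the threshold whose groups do not overlap, or by p alone for the interaction, where IDs that did not pass are said not to. Chromosomes and subgenomes were read from the IDs, and shares of called IDs were compared with two-sided Fisher's exact tests adjusted over 116 tests.

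Alternatives were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 1 FPKM, median-ratio scaling, quantile normalization, a fit to the compared groups only, a term for the replicate number, library weights, a minimum log2 change of 1, a threshold of 0.01 for the chromosome shares, and each library left out in turn. Fits without combinations of 3798 control 3, 3798 silenced 4 and JX silenced 4 were added after the data were seen. Genes called on/off were at or above 1 FPKM in each of 8 libraries and more than 8-fold below the lowest of these in each of the other 8. This definition, too, was set after the data were seen. Splits of the samples were counted in full (35) for comparisons of 2 groups and drawn (100, with the real one) for the mean and the interaction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these and for the figures.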

Results

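Messenger RNA from the shoot apex of upland cotton (Gossypium hirsutum) seedlings was sequenced in 16 libraries. The libraries form 4 groups of 4, from 2 strains that differ in fruiting branch type, each as a control group and as a group in which GhBRC1 was silenced. Strain 3798 is nulliplex-branch, a form in which flowers are borne on the main stem without an elongated fruiting branch, and Jinxian-short branch, called JX here, has short fruiting branches. Silencing was by virus-induced gene silencing, in which a recombinant virus carries a fragment of a plant gene and the plant's own RNA interference lowers the matching transcript. BRC1 is a TCP-family transcription factor known in other plants to restrain the outgrowth of axillary buds. The labels do not say what the control plants received, or whether the 4 libraries of a group came from separate plants, so p-values measure the spread between these samples, which may be technical.

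Values were available for 70422 gene IDs as FPKM. Of these, 30060 IDs name a chromosome of the A subgenome, 31094 a chromosome of the D subgenome and 1143 a contig, and 8125 are called newGene with no position. None of the sources used here pairs the IDs with gene names, so genes are given by ID and the level of the silenced GhBRC1 transcript was not analysed here. The labels of silenced and control libraries are therefore used without a check by the target gene. A change on silencing below means a difference between libraries so labelled, whatever its cause. Total FPKM per library ranged from 552185 to 603167, and between 9.91% and 12.5% of IDs were listed at 0. Sequencing depth relative to 3798 control 1 ranged from 0.909 in JX control 2 to 1.33 in 3798 silenced 3, with group means of 1.05 and 1.12 in 3798 controls and silenced and of 1.002 and 1.11 in JX controls and silenced. Absolute depth is unknown.

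The silenced libraries numbered 1 to 3 and the JX controls lay at opposite ends of the first principal component, which held 43.4% of the variance. The 4 JX controls scored between 88.8 and 105, and the 6 silenced libraries numbered 1 to 3 scored between -83.4 and -54.9. The 3798 controls 1, 2 and 4 stood apart on the second component (19.4% of the variance), at 85.5 to 96.2. Other libraries lay away from their groups. Library 3 of the 3798 controls was at 76.0 and 14.1 on the 2 components and had a mean correlation of 0.962 with the JX controls, against 0.931 with the other 3798 controls. Library 4 of the 3798 silenced group (-22.8) and library 4 of the JX silenced group (4.43) lay toward the JX controls on the first component.

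**Figure D1:**
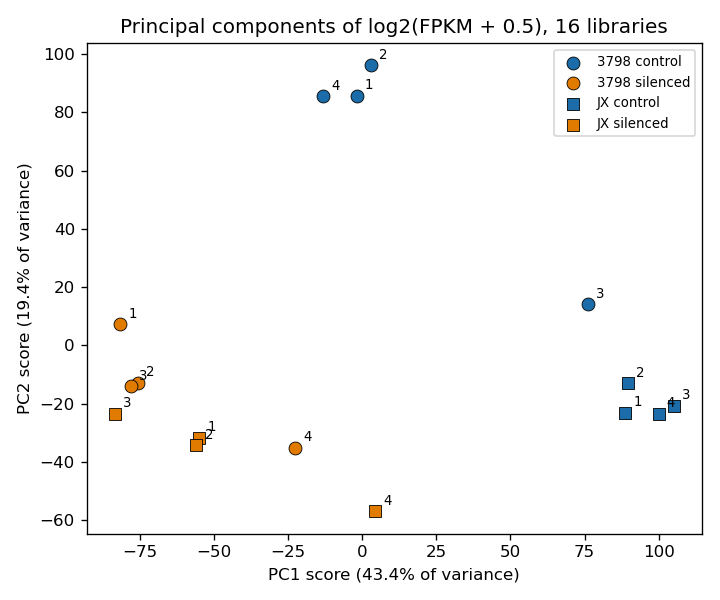
Scores of the 16 libraries on the first principal component (horizontal axis, 43.4% of variance) and the second (vertical axis, 19.4%) of log2(FPKM + 0.5) over 55040 genes, with circles for 3798, squares for JX, blue for control, orange for silenced and the replicate number beside each point. Library 3 of the 3798 controls, at 76.0 and 14.1, lies nearer to the JX controls than to the other 3798 controls.

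The first question is which transcripts differed between libraries labelled silenced and control in 3798. Gh_A09G027500, on chromosome A09, rose from a mean of 0.0137 ± 0.0274 FPKM (SD, n = 4) to 30.1 ± 3.40 FPKM (SD, n = 4). Gossypium_hirsutum_newGene_9749 was listed at 0 in all 4 controls and at 10.4 to 16.3 FPKM in the silenced libraries. Gh_A07G084200, on chromosome A07, was at 21.4 to 27.5 FPKM in the controls and listed at 0 in all 4 silenced libraries. Gossypium_hirsutum_newGene_2353 fell from 52.2 ± 4.28 FPKM (SD, n = 4) to 0.0990 ± 0.114 FPKM (SD, n = 4). The log2 change on the log2(FPKM + 0.5) scale, which understates changes of low genes, was 5.89 (SE 0.108) for Gh_A09G027500 and -6.47 (SE 0.127) for newGene_2353, both with an adjusted p of 1.1e-14 by limma. All 4 genes belong to a set of 157 that were at or above 1 FPKM in every library of one label and more than 8-fold below the lowest of these in every library of the other label, across both strains. Such genes could also mark different genotypes of the libraries under the labels, a hypothesis taken up at the end.

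Of 55040 genes tested, 7040 differed between silenced and control libraries of 3798 by limma at an adjusted p under 0.05, 4133 higher and 2907 lower in silenced. At least a 2-fold change was seen in 2293 of them (1323 higher, 970 lower) and at least a 4-fold change in 538. The groups of 4 did not overlap for 16.2% of genes, where chance gives 2.86%. The median standard error of a log2 change was 0.164. Fitted on the 8 libraries of 3798 alone, limma called 4675 genes, and with libraries weighted by their spread 10695. In the latter fit 3798 control 3 had the lowest weight, 0.283.

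In JX the same comparison gave the same 4 leading IDs. Gh_A09G027500 rose from 0.0108 ± 0.0217 FPKM (SD, n = 4) to 33.0 ± 3.38 FPKM (SD, n = 4), with a log2 change of 6.03 (SE 0.108, limma adjusted p = 7.5e-15). Gossypium_hirsutum_newGene_9749 was listed at 0 in all 4 controls and at 14.8 to 17.3 FPKM in the silenced libraries. Gh_A07G084200 was at 16.9 to 23.0 FPKM in the controls and listed at 0 in all 4 silenced libraries. Gossypium_hirsutum_newGene_2353 fell from 37.6 ± 3.46 FPKM (SD, n = 4) to 0.0295 ± 0.0347 FPKM (SD, n = 4), a log2 change of -6.17 (SE 0.127, limma adjusted p = 2.3e-14). Across all genes 15570 differed by limma, 8039 higher and 7531 lower in silenced. Which direction had more calls depended on the setting: quantile normalization gave 7599 higher and 8103 lower, and leaving out JX silenced 4 gave 8860 and 9178. Of these, 4628 changed at least 2-fold (2508 higher, 2120 lower) and 787 at least 4-fold. The groups did not overlap for 29.7% of genes, against 2.86% by chance.

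**Figure D2:**
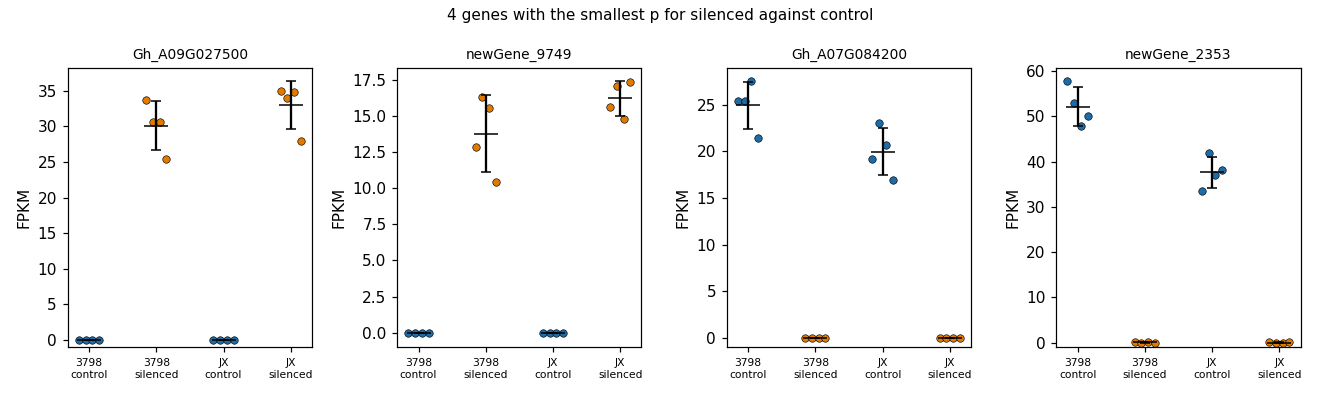
FPKM (vertical axis) of the 4 IDs with the smallest p for silenced against control, in each of the 16 libraries (points) by group, with the mean (horizontal bar) and SD (error bar) of the 4 libraries of a group. Gh_A09G027500 and newGene_9749 were near or listed at 0 in controls and reached 25.5 to 35.0 and 10.4 to 17.3 FPKM in silenced libraries, and Gh_A07G084200 and newGene_2353 did the opposite.

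Averaged over both strains, 15799 genes differed between silenced and control libraries by limma, 8704 higher and 7095 lower in silenced, and 2811 changed at least 2-fold. The 4 IDs with the smallest p were again Gh_A09G027500, newGene_9749, Gh_A07G084200 and newGene_2353. The log2 change averaged over strains was 5.96 (SE 0.0760) for Gh_A09G027500 and -6.32 (SE 0.0896) for newGene_2353, with limma adjusted p of 3.9e-17 and 6.7e-17.

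Genes that changed in one strain tended to change in the same direction in the other. Of the genes called in each strain, 2513 were higher in silenced libraries of both, where independent lists would share 604, and 1620 were lower in both, where independent lists would share 398. In 52 genes the calls were opposite. The correlation of the log2 changes across the 55040 genes was 0.64 (Pearson) and 0.41 (Spearman), and genes are not independent replicates. The log2 changes of the 2 strains share no library. Their calls share each gene's estimate of the spread, so the lists can overlap beyond independent lists for that reason too. The log2 changes had the same sign in 61.4% of all genes, or in 54.6% without 3798 control 3. Without 3798 control 3 the correlation was 0.50 (Pearson) and 0.23 (Spearman), the shared calls were 2281 higher (823 for independent lists) and 1445 lower (574), and 753 calls were opposite.

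**Figure D3:**
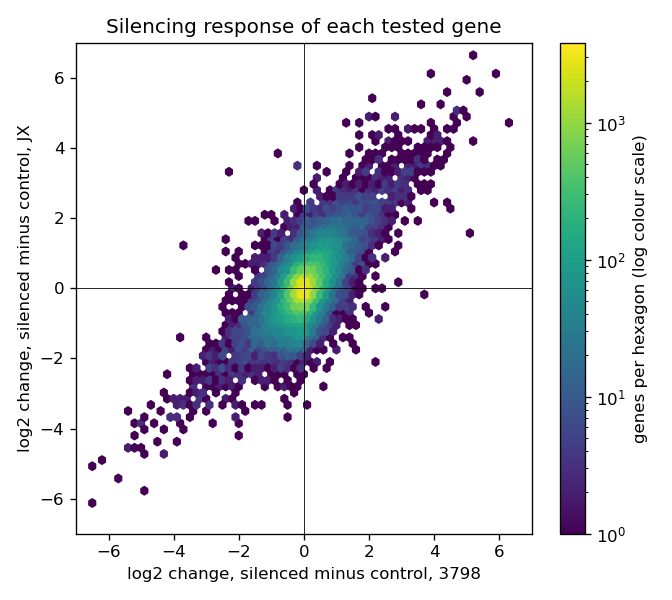
Log2 change on silencing, silenced minus control on the log2(FPKM + 0.5) scale, in 3798 (horizontal axis) and JX (vertical axis) for 55040 genes, as counts of genes per hexagon on a log colour scale. The cloud runs from lower left to upper right, with a Pearson correlation of 0.64 across genes.

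Whether the response differed between the strains was tested as the interaction of strain and silencing. For 2 IDs the interaction passed limma's adjusted p of 0.05. Gossypium_hirsutum_newGene_8863 fell on silencing in 3798, from 12.2 ± 0.939 to 9.15 ± 0.790 FPKM (SD, n = 4), and rose in JX, from 7.63 ± 0.510 to 11.2 ± 0.591 FPKM (SD, n = 4), a difference in log2 change of 0.92 (SE 0.119, limma adjusted p = 0.029). Gh_A05G057400, on chromosome A05, was at 87.1 ± 7.63 and 108 ± 8.29 FPKM in 3798 controls and silenced and at 166 ± 32.9 and 83.5 ± 5.42 FPKM in JX (SD, n = 4), a difference of -1.28 (SE 0.168, limma adjusted p = 0.029). The next 2 by p, Gh_A07G004200 at 0.93 and Gh_Contig00435G000100 at -1.77, did not pass (limma adjusted p = 0.078 for both). At an unadjusted p under 0.05 there were 11946 genes, where 2752 are expected by chance. Without 3798 control 3, 8569 genes passed, 3660 with a higher and 4909 with a lower change in JX, and without any 1 of the 15 other libraries 0 to 18 passed. With libraries weighted by their spread, 10210 passed.

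The control libraries of the strains differed in 16416 genes by limma, 9700 higher and 6716 lower in JX, of which 3098 differed at least 2-fold (2056 higher, 1042 lower). Scaling moved this balance, to 8732 higher and 7739 lower with median-ratio scaling and to 8263 and 7919 with quantile normalization. Gh_Contig00435G000100 was at 7.07 ± 0.766 FPKM in JX and 1.64 ± 0.307 FPKM in 3798 (SD, n = 4), a log2 difference of 1.83 (SE 0.202, limma adjusted p = 0.0013). Gh_A13G058400, on chromosome A13, was higher in JX by 0.59 (SE 0.0716, limma adjusted p = 0.0015), at 12.7 ± 0.804 against 8.26 ± 0.418 FPKM (SD, n = 4). Gh_D01G109900, on chromosome D01, was at 4.17 ± 0.322 FPKM in JX and 11.2 ± 2.22 FPKM in 3798 (SD, n = 4), and Gh_A02G041300, on chromosome A02, at 5.20 ± 1.02 and 29.3 ± 7.37 FPKM (SD, n = 4). Their log2 differences were -1.31 and -2.36 (SE 0.138 and 0.249, limma adjusted p = 0.0013 for both). The groups did not overlap for 25.1% of genes, against 2.86% by chance. Without 3798 control 1, 2 or 4 the count was 11034, 10650 or 11522, and without 3798 control 3 it was 21330.

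Between the silenced libraries of the strains, a comparison added after the data were seen, limma called 0 of 55040 genes. At an unadjusted p under 0.05 there were 4345, where 2752 are expected by chance, and the groups did not overlap for 4.45% of genes, against 2.86% by chance. Leaving out any 1 of the 16 libraries gave between 0 and 4 genes. Whether the strain difference was smaller in silenced than in control libraries is the interaction above, with 2 genes over all libraries and 8569 without 3798 control 3.

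Shares of called IDs were compared between the A and D subgenomes, and between each chromosome and all other tested IDs. The other IDs include newGene and contig IDs. On silencing in JX, on average over strains and between controls, both kinds were called less often than A or D chromosome IDs. This lowers the share of the others there, so a chromosome that passed need not differ from the other chromosomes. Chromosomes were not tested against the other chromosomes only. On silencing in 3798 12.4% of A and 13.1% of D chromosome IDs were called, in JX 29.0% and 29.2%, and between controls 31.6% and 31.8%, and none of these differences passed Fisher's exact test adjusted over 116 tests (adjusted p from 0.081 to 0.86). Chromosome D05 had the highest share of called IDs on silencing in JX, 32.4% against 28.1% of all others (two-sided Fisher's exact test, adjusted p = 1.5e-05), and on average over strains, 32.7% against 28.5% (adjusted p = 3.3e-05). In 3798 the share on D05 was 14.3% against 12.7% and did not pass (adjusted p = 0.081). Between the controls of the strains D05 passed as well, 32.6% against 29.7% (adjusted p = 0.015), as did A13 at 33.1% and D07 at 32.9% against 29.7% (adjusted p = 0.047 for both). With genes called at an adjusted p under 0.01, none of D05, A13 and D07 passed between controls (adjusted p = 0.20, 0.53 and 0.17), and A07 did, 16.4% against 13.5% (adjusted p = 0.0090). At that threshold all A and D chromosome IDs were called at 14.8% and 14.6%, and newGene IDs at 4.77%. For silencing averaged over strains D10 also passed against all other IDs, 31.8% against 28.6% (adjusted p = 0.047). In that comparison all A and D chromosome IDs were called at 29.0% and 29.7%. At the threshold of 0.01, D05 and D10 passed on silencing in JX and on average (Fisher's exact test, adjusted p from 0.00050 to 0.0090). There D10 had the highest share of the chromosomes, 16.81% in JX and 20.55% on average, against 16.75% and 20.29% for D05. The IDs called newGene were called less often than the rest between the controls of the strains, 14.7% against 31.6%, and on silencing in JX, 22.0% against 29.0% (Fisher's exact test, adjusted p = 2.7e-170 and 5.0e-28). On silencing in 3798 the shares were 13.2% and 12.7% (adjusted p = 0.56), and with genes called at an adjusted p under 0.01 newGene IDs were called more often, 8.02% against 6.14% (adjusted p = 5.4e-06). In these tests each gene counts as independent, which genes of 1 library set are not.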

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

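All tests weighed here, including the counts of other splits of the samples, were chosen after the results were seen. Among the flagged values, 8 come from 1 library of a group of 4 far from the other 3, out of 68 groups of values checked, of which chance flags about 5%. The remaining 2 were flagged because the response to silencing differed between the strains. Among the 8, Gh_A09G027500 in 3798 control 2 and in JX control 3 had the 3 other libraries of the group listed at 0. Any value above 0 is flagged there, so the 5% does not hold for them.

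Library 3 of the 3798 controls was flagged on the second principal component, at 14.1, where the next library of its group was at 85.5. The tables argue against an exchange with a JX control, since every JX control correlated better with the JX controls than with the 3798 controls, by at least 0.0433. A mixture of RNA from both control groups stays open: genes higher in 3798 controls gave a share of 3798 RNA of 11.5% and genes higher in JX controls 39.4%, a difference of 27.8 percentage points that lay 1.81 prediction SDs from the 7 other controls, too few to decide. A JX control with a wrong label should give shares within the range of the 4 JX controls. The shares lay above the highest of these, 6.45% for genes higher in 3798 controls and 17.2% for genes higher in JX controls. They lay 2.45 and 2.08 prediction SDs above the 4 JX controls, too few to tell a wrong label apart from a 3798 plant in another state. A difference between plants within the strain stays open and was not tested.

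Library 4 of the JX silenced group was flagged for genes seen in it alone, at least 1 FPKM there and more than 8-fold lower in each of the 15 others: 58, where the next highest of its group had 9. RNA of the control libraries mixed into it should bring all genes of those libraries. This was examined in 120 genes at or above 1 FPKM in every control and more than 8-fold below the lowest control in the silenced libraries numbered 1 to 3. Of these, 51.7% stayed under 5% of the control level in JX silenced 4, while 50 exceeded 20%, with a median of 41.9%. The same 120 genes were all under 5% in 3798 silenced 4. The 58 genes seen in it alone are consistent with RNA of a further genotype in this library, the highest of the 15 other libraries having 9. No biological explanation was tested, and a shift shared with other libraries, described next, stays open beside it.

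Library 4 of the 3798 silenced group was flagged on the first principal component, at -22.8, with the next library at -75.5. Its deviations from the group mean across genes correlated with those of 3798 control 3 (r = 0.44) and JX silenced 4 (r = 0.36), and those of the latter 2 with each other (r = 0.44), the 3 highest values of all pairs of libraries from different groups, so these libraries deviated in part together. In JX silenced 2, 8028 genes were listed at 0, with 7141 in the next library of its group. JX silenced 2 also had the lowest relative depth of its group, 0.941 against 1.10 to 1.26 in the others. Gh_A09G027500 was at 0.0548 FPKM in 3798 control 2 and at 0.0434 FPKM in JX control 3, with 0 listed in the others of each group, and at 27.9 FPKM in JX silenced 4, with the next at 34.0. Gh_A05G057400 was at 75.4 FPKM in JX silenced 3, with the next at 85.7.

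The log2 change on silencing differed between the strains, JX minus 3798, by 0.92 for Gossypium_hirsutum_newGene_8863 and by -1.28 for Gh_A05G057400. Other splits of the samples do not decide whether chance gave this count. They exchange strains within controls and within silenced libraries, so a split that keeps the controls by strain carries the strain difference of the controls into the interaction. Of 100 splits, 7 with the real one gave 2 or more genes, and the highest other, 7628, came from a split with all JX controls on one side and at least 3 of the 3798 controls on the other. Without 3798 control 3, 5 of 100 splits with the real one gave as many as the real 8569, the highest other 15458, and all 4 others kept the controls by strain, where the highest of the remaining splits gave 7104.

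For the other counts, 1 of 35 splits, the real one, gave as many genes for silencing in 3798 (7040, highest other 2365) and in JX (15570, highest other 2). The same held for the strain difference in controls (16416, highest other 8128). For silencing averaged over strains it was 1 of 100 splits (15799, highest other 2189). A share of 1 in 35 or 1 in 100 is the lowest these tests can give, so a chance split of the samples is less likely but not excluded. The split with 8128 genes set 3798 controls 1, 2 and 4 and JX control 2 against the rest, which places 3798 control 3 with JX. Between the silenced libraries of the strains the real split gave 0 genes, and the highest other of the 35 gave 12. With a real count of 0 every split gives as many or more, so these splits decide nothing about chance.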

How the results depend on the processing

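The comparison of the silenced libraries, the fits described as added and all counts of on/off genes were chosen after the data were seen, and the other alternatives before. BRC1-type genes and gene lists were not run under any alternative for lack of gene names. Absolute depth is unknown, and so are its limits. Of the counts, correlations and subgenome odds under alternatives, 166 values stayed within 1.5 times of the reported count, within 0.1 of the reported correlation, or on the same side of the threshold, and 40 moved. The IDs named for silencing and for the controls kept direction and call in all 88 combinations of ID and fit of each comparison. For the interaction, the 2 IDs that passed lost the call in 22 of 44 combinations of ID and fit, and the 2 that did not pass gained it in 6 of 44, with no change of direction. In JX the calls on silencing turned to more lower than higher with median-ratio scaling (7812 higher, 7816 lower), quantile normalization (7599 and 8103), the compared groups only (7573 and 7781), library weights (10649 and 10961), without JX silenced 4 (8860 and 9178) and in all 3 added fits.

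Asking for a log2 change of at least 1, which by construction keeps fewer genes, left 2293 genes for silencing in 3798, 4628 in JX, 2811 on average, 3098 between controls and 1 for the interaction. In the fit to the compared groups only, 4675 genes changed in 3798 and 2 differed between silenced libraries. Library weights gave 10695 in 3798, 10210 for the interaction and 3 between silenced libraries. Without the low-value filter 4 differed between silenced libraries. The cause was not tested for these.

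Leaving out 1 library at a time gave 4704 to 8580 genes in 3798, 10666 to 18038 in JX, 13448 to 17574 on average, 10650 to 21330 between controls, 0 to 4 between silenced libraries and 0 to 8569 for the interaction, and a correlation of 0.50 to 0.71. The 8580 in 3798, the 21330 between controls, the 8569 and the 0.50 came without 3798 control 3, and the 10650 without 3798 control 2. Of the others, the interaction had 18 genes without JX silenced 4, 7 without 3798 silenced 1, 5 without JX silenced 1, 1 without 3798 control 2, JX control 3 or JX silenced 3, and 0 without 3798 control 1 or 4, 3798 silenced 2 or 3, JX control 1 or 2 or JX silenced 2. Between silenced libraries the count was 4 without JX silenced 1, 3 without 3798 silenced 4, 2 without JX silenced 4 and 1 without JX silenced 3 or JX control 4. On/off genes numbered 230 without JX silenced 4, and 208 and 132 at a 4-fold and a 16-fold gap.

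In the added fits, leaving out 3798 control 3 and JX silenced 4 gave 12532 genes for the interaction, 2 between silenced libraries and a correlation of 0.48. Leaving out both silenced libraries numbered 4 gave 8 and 4 genes, and leaving out all 3 gave 10410 and 7. The cause was not tested.

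With the replicate number as a block, 0 genes passed for the interaction, and the block left 6635, 14885, 15220 and 15570 genes for 3798, JX, their mean and the controls. No pairing by number was evident: deviations of same-numbered libraries of different groups correlated between -0.37 and 0.36 (median 0.020, 24 pairs). Of 16 libraries, 4 correlated best with one of their own number. The highest value joins 3798 silenced 4 and JX silenced 4, which both lay away from their groups. The deposited columns run through all groups of one number before the next, so a block by number is not excluded.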

Other observations

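The tests of the on/off genes were all chosen after the result was seen, on the data that showed it.

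Among the genes that separated silenced from control libraries were 157 that behaved as on or off in both strains. At or above 1 FPKM in all 8 libraries of one label and more than 8-fold below the lowest of these in all 8 of the other, 95 were on in silenced and 62 on in control libraries, or 111 and 119 without JX silenced 4. Of the 95, 39 were listed at 0 in all 8 controls, and of the 62, 18 were listed at 0 in all 8 silenced libraries. IDs called newGene made up 77 of the 157 (49.0%), against 10.3% of the other tested IDs (two-sided Fisher's exact test, p = 2.8e-34). Between the strains, over all 16 libraries, 0 genes met the same rule, and between the controls of the strains 0, or 46 without 3798 control 3, of which 1 was a newGene. Between the silenced libraries of the strains 0 genes met the rule, with or without JX silenced 4.

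Failed estimates scattered over the libraries without regard to label do not account for the on/off genes. Among the 6435 splits of the 16 libraries into 8 and 8, the highest count of any other split was 1. Failed estimates that follow the label would give the same counts and stay open. A graded response to silencing stays open as well. It was examined in 3798 silenced 4 and JX silenced 4, which lie toward the controls. On/off genes are picked for a large and steady change with an off side near 0. Such genes could deviate less than others under a graded response too, so the comparison cannot decide. On/off genes defined without these libraries kept more of the silenced level than other genes changed at least 4-fold. For genes higher in silenced libraries the medians were 81.2% against 41.6% in 3798 silenced 4 and 74.0% against 55.1% in JX silenced 4, and the smallest of the 4 differences over libraries and directions was 8.79 percentage points (permutation p at most 0.00169 over genes, which are not independent, with 1e-05 the smallest that 100000 resamples can give). A candidate explanation is that the libraries labelled silenced and control come from different genotypes, such as other seed lots or exchanged labels, which should put on/off genes side by side, and 8 pairs of the 78 on/off genes with a chromosome ID were neighbours within 2 positions, against a median of 0 (95% of draws 0 to 1) for random genes of like level and 1 (0 to 4) for other strongly changed genes. This remains a hypothesis, since neighbours can also be tandem copies under shared control, an all-or-none response to silencing or to the virus was not tested, and the target gene was not analysed here.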
